A study of Mus musculus with 10 samples.

How the data were processed

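The series measured messenger RNA in 10 cultures of primary cortical microglia from CD-1 mouse pups, treated for 24 h with PBS (4 libraries) or 1 µg of serum sEVs from sham-operated (3) or SNI (3) mice, per the labels. Per the labels' protocols, total RNA was isolated with a column kit and DNase, and libraries were made with a stranded poly(A) mRNA kit. Per the submitters' processing notes, bcl2fastq, BWA, Subread and featureCounts 2.0.2 were used with the mm10 build. The notes give neither the role nor the order of these tools, nor the annotation, nor how reads of near-identical copies were divided.

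The deposited expression table holds TPM made by the authors, per gene length and scaled to a total of 1000000 in each of the 10 columns, for 32074 gene symbols, 1 column per library. TPM keeps no read totals, so the depth per library is unknown, and no count test, counting interval or limit of detection was computed. The deposited table of differential genes holds the authors' signed fold change and a false discovery rate (FDR, read as an adjusted p-value) for 3 comparisons of 2375 genes, per the file headers. The test behind it is not stated. Of the symbols, 30956 matched the RefSeq gene table and 25293 GENCODE vM21, which gave the coordinates on GRCm38 (mm10).

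Groups came from the treatment labels. With R 4.3.3 and limma 3.58.1, log2(TPM + 1) of the 14806 genes with a mean of at least 1 TPM over all libraries was fitted with 1 mean per group and a spread shared by the 3 groups (eBayes with a trend). Each of the 3 comparisons was tested two-sided with Benjamini-Hochberg adjustment over the genes tested, with a threshold of 0.05. Fold changes are on the scale of TPM + 1, so they understate ratios of genes near 0. Errors beside TPM are SD between libraries, and beside log2 fold changes the standard error of the fit. The labels call the libraries biological replicates. P-values measure the spread between them and cover no other culture or vesicle preparation.

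Before the data were examined, 31 gene lists were fixed. They cover microglial states, inflammation, interferon, metabolism, stress, matrix, markers of other cells and transcripts of blood and liver. The 24 lists with at least 5 tested members were tested with limma's camera (preset inter-gene correlation of 0.01), beside camera with an estimated correlation and fry, with adjustment over the 24 lists. Members were also adjusted over the list alone. Genes named in the text follow a rule fixed at the same time. It takes the 10 largest rises and falls per comparison among called genes whose groups do not overlap and whose mean is at least 2 TPM, up to 4 members per list by smallest p (2 by mean where none passed), and the 5 largest of each direction in the deposited table. Predicted genes are not named, and members of lists without a call may be given as counts. Genes outside the rule are said to be chosen after their values were seen. A few genes that the rule takes are not reported here.

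The overlap of both vesicle effects against PBS was set beside 100 simulated draws of unchanged groups against the same PBS libraries, the overlap of independent lists, and the 6 splits of the PBS libraries 2 and 2. The numbers in the labels were checked for pairing by the correlation across genes of deviations from the group mean. Same-numbered PBS and SNI-sEV libraries correlated at 0.154 to 0.363 in 3 of 3 pairs and were taken as paired by these data. Same-numbered PBS and sham-sEV pairs (-0.0176 to 0.0512) and sham-sEV and SNI-sEV pairs (0.0172 to 0.0772) were not. Different-numbered PBS and SNI-sEV pairs ranged from -0.351 to 0.220 (mean -0.0815). For different-numbered PBS and sham-sEV pairs the range was -0.270 to 0.161. These ranges overlap that of the pairs taken as paired, so the pairing is not certain. The main fit leaves it out, and only the replicate block uses it.

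Alternatives were pseudocounts of 0.1 and 0.5, no filter, a mean of at least 5 TPM, median-of-ratios scaling, quantile normalization, robust spread estimates, sample weights, only the 2 groups compared, the replicate number as a block, and each library left out. Other alternatives, chosen after seeing the data, left out pseudogenes, left out PBS libraries 1 and 2, or fitted the replicate block to the PBS and SNI-sEV libraries alone, and median-of-ratios scaling was then also applied to the gene lists. The planned count tests were not run because the table holds no counts.

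The fit was tested on simulated data of the 14806 genes. Per comparison, 66 or 67 genes were changed at each fold, drawn from genes at about 2 TPM or more in PBS. The rest were left unchanged, so recovery of genes low in PBS was not tested. For SNI sEV against sham sEV the fit recovered 97.0%, 95.5% and 100% of genes changed 1.5-, 2- and 4-fold. For SNI sEV against PBS it recovered 91.0%, 100% and 100%, and for sham sEV against PBS 86.6%, 100% and 98.5%. In the 3 comparisons 4, 7 and 6 unchanged genes were called. The list test recovered 3 of 3 shifted lists and called 0 of 69 others by camera. The simulated genes varied independently of each other, so this does not cover false calls in lists of correlated genes. In the data the estimated correlation ranged from -0.00483 for border macrophage markers to 0.735 for interferon-stimulated genes. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.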

Results

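RNA sequencing measured transcript levels in primary cortical microglia, the resident macrophages of the brain, grown from newborn CD-1 mouse pups. For 24 h the cells received 1 µg of small extracellular vesicles (sEVs), membrane particles that cells release into body fluids, or phosphate-buffered saline (PBS) as a control. The vesicles came from the serum of mice with spared nerve injury (SNI) or of sham-operated mice. SNI is a model of neuropathic pain in which branches of the sciatic nerve are cut and a neighbouring branch is left intact. The groups held 4 PBS, 3 sham-sEV and 3 SNI-sEV libraries, which the labels call biological replicates without saying whether each had its own culture or vesicle preparation. The values are TPM, shares of the transcripts scaled to a total of 1000000 per library, for 32074 genes. This unit keeps no sequencing depth, so the depth is unknown and no counting interval is given. Between 14577 and 14973 genes reached 1 TPM in the PBS libraries, 14117 to 14166 in the sham-sEV libraries and 14869 to 14900 in the SNI-sEV libraries. The tests cover the 14806 genes with a mean of at least 1 TPM over the 10 libraries.

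The sham-sEV cultures stood apart from both other groups, while the SNI-sEV cultures lay close to PBS. The first principal component held 85.9% of the variance, with the sham-sEV libraries at 70.5 to 72.0, the SNI-sEV libraries at -24.7 to -20.4 and the PBS libraries at -38.7 to -32.7. Across genes, log2(TPM + 1) correlated at 0.908 to 0.917 between sham-sEV and PBS libraries, and at 0.982 to 0.993 between SNI-sEV and PBS libraries. Within groups the lowest correlation was 0.996 for sham sEV, 0.995 for SNI sEV and 0.987 for PBS. Genes are not independent replicates. The labels give no batch, so a batch shared by a whole group cannot be told apart from the treatment.

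**Figure D1:**
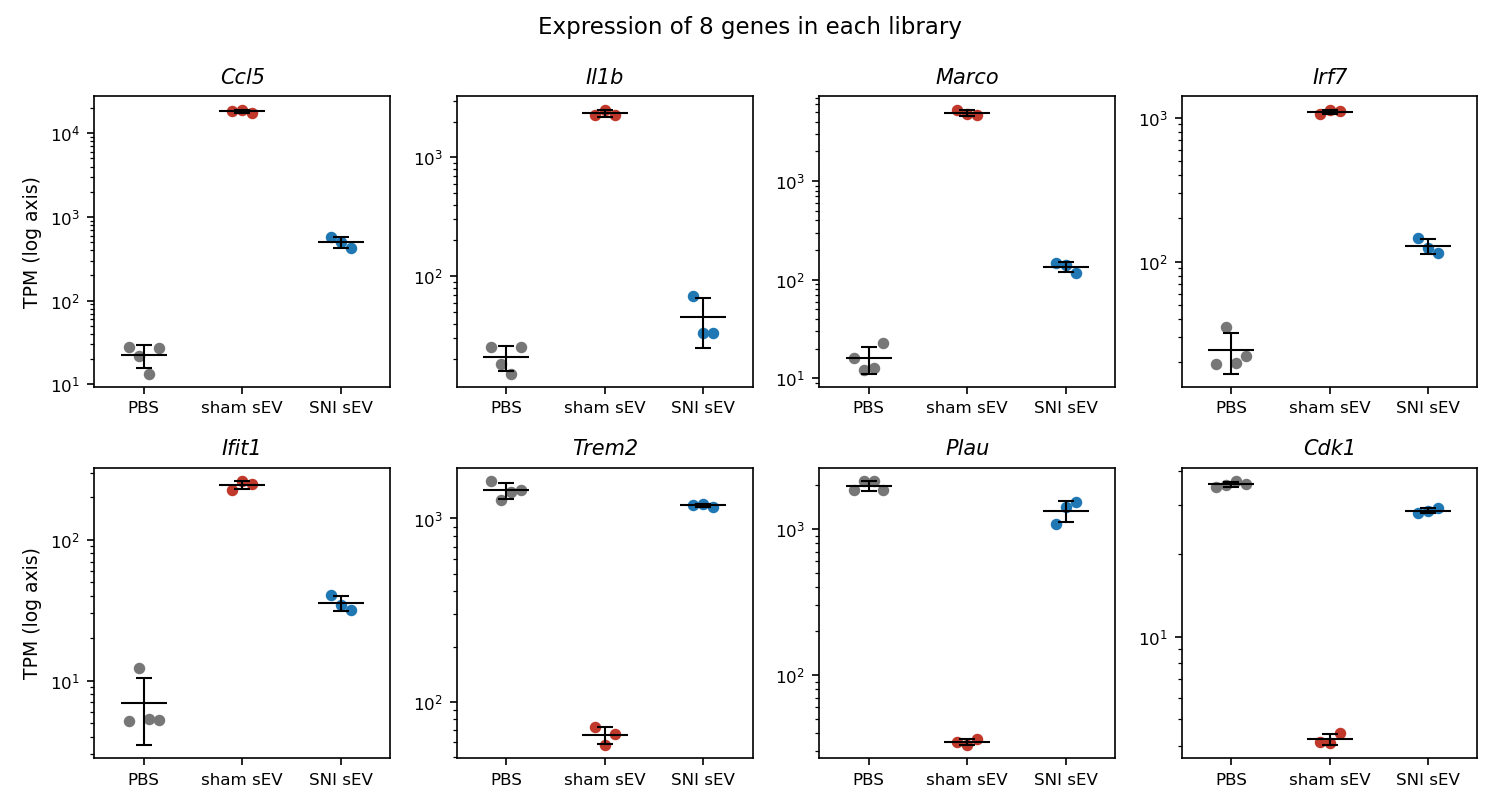
TPM of 8 genes (log axis) in each library of the PBS (n = 4), sham-sEV (n = 3) and SNI-sEV (n = 3) groups. Points are libraries, and the horizontal bar with whiskers is the mean ± SD. Ccl5 averaged 22.6 TPM in PBS, 18328 TPM in sham sEV and 501 TPM in SNI sEV, while Trem2 averaged 1422, 65.9 and 1181 TPM.

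Sham sEVs against PBS asks how the cells responded to vesicles from animals without the nerve injury. Inflammatory and interferon-response genes rose in the sham-sEV cultures, and proliferation genes and many genes of the microglial state fell. Ccl5, a chemokine that attracts T cells and monocytes, averaged 18328 ± 784 TPM (SD, n = 3) against 22.6 ± 6.73 TPM in PBS (SD, n = 4), 806-fold higher on the scale of TPM + 1. The scavenger receptor Marco rose 296-fold to 4903 ± 330.5 TPM, and the acute-phase gene Saa3 from 612 ± 115 to 61044 ± 2383 TPM. In the other direction, Plau, which encodes the protease urokinase, was at 34.8 TPM against 1981 ± 163 TPM in PBS, and the lipid-sensing receptor Trem2 at 65.9 ± 7.26 against 1422 ± 144 TPM.

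The 10 largest rises were Ccl5, Marco, the dicarboxylate transporter Slc13a3, the cytokines Il6, Il1a and Il1b, the siderophore-binding protein Lcn2, the inhibitory sialic acid receptor Siglece, Saa3 and the formyl peptide receptor Fpr1, from 92.5-fold for Fpr1 to 806-fold for Ccl5. Il6 went from 0.0672 ± 0.0742 TPM in PBS to 115 ± 7.38 TPM (log2 fold change 6.77 ± 0.08 SE, limma adjusted p = 1.0e-12), Il1a from 1.88 to 309 TPM, Il1b from 21.0 to 2341 TPM and Lcn2 from 17.2 to 1860.0 TPM. The 10 largest falls were Plau, the leukocyte actin-binding protein Lsp1, the Wnt modulator Dkk2, the prostaglandin-degrading enzyme Hpgd, Rgs2, Rasgrp3, Pcp4l1, Trem2, Crip1 and Mamdc2, from 19.3-fold for Mamdc2 to 55.2-fold for Plau. Spp1, which encodes osteopontin and was chosen after its values were seen, fell from 39304 to 4201 TPM. On GRCm38, the build of the files, GENCODE places Ccl5 at chromosome 11, 83525778 to 83530518, minus strand, Marco at chromosome 1, 120474538 to 120505024, minus strand, Plau at chromosome 14, 20836660 to 20843385, plus strand and Trem2 at chromosome 17, 48346401 to 48354147, plus strand.

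All 20 tested pro-inflammatory cytokines and chemokines rose (camera adjusted p = 2.5e-22; 0.0075 with an estimated correlation), among them Tnf (74.0 to 544 TPM) and Ptgs2, the inducible prostaglandin synthase (0.851 to 64.9 TPM). All 15 NF-kappaB feedback and target genes rose (camera adjusted p = 1.3e-15; adjusted p = 0.082 with an estimated correlation), including Traf1 (62.2-fold), the mitochondrial superoxide dismutase Sod2 (44.9 to 597 TPM) and the inhibitor of apoptosis Birc3 (5.78-fold). All 32 type I interferon-stimulated genes rose, with a median log2 fold change of 3.06 (camera adjusted p = 2.7e-28; adjusted p = 0.11 with an estimated correlation). Oasl1 rose 49.4-fold, Zbp1, a sensor of Z-form nucleic acid, 30.8-fold, and the guanylate-binding proteins Gbp2 and Gbp3 19.7-fold and 19.9-fold. The counts of these 3 lists adjusted over the list alone were the same, 20, 15 and 32.

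Genes of antigen processing and presentation went both ways: 12 of 18 tested genes rose and 5 fell, and 12 and 5 did so adjusted over the list alone (camera adjusted p = 1.4e-06; adjusted p = 0.094 with an estimated correlation). Cd40, a co-stimulatory receptor, rose 10.4-fold and the class I gene H2-K1 3.85-fold from 754 TPM. The 5 that fell, chosen after their values were seen, were Cd86 and the class II genes H2-DMa, H2-DMb1, H2-Ab1 and H2-Aa. The class II invariant chain Cd74, also chosen after its values were seen, rose 1.77-fold. Cd86 did not pass under median-of-ratios scaling or quantile normalization (limma adjusted p = 0.18 and 0.11). How reads of near-identical copies such as the class I genes were divided is not stated. H2-DMb1 went from 23.9 to 8.53 TPM and H2-Aa from 2.60 to 1.04 TPM. Of 18 complement and phagocytic receptor genes, 11 rose and 2 fell, or 12 and 2 adjusted over the list alone (camera adjusted p = 1.5e-05; 0.039 with an estimated correlation). Under median-of-ratios scaling 15 rose and 2 fell. Complement C3 rose from 114 to 1624 TPM and the high-affinity Fc receptor Fcgr1 from 67.6 to 387 TPM, while the lysosomal marker Cd68 fell from 2980.1 to 1056 TPM.

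Homeostatic microglia genes, which mark the resting state, fell in 14 of 17 cases, also adjusted over the list alone, and 1 rose (camera adjusted p = 0.024; adjusted p = 0.25 with an estimated correlation). The fractalkine receptor Cx3cr1 fell from 345 ± 32.4 to 50.9 ± 4.99 TPM, whereas Fcrls rose from 18.8 to 265 TPM. Disease-associated microglia genes, the set that rises in neurodegeneration models, fell in 16 of 20 cases and rose in 2, with the same counts adjusted over the list alone (camera adjusted p = 0.00027; adjusted p = 0.18 with an estimated correlation). Besides Trem2, the tetraspanin Cd9 fell from 972 to 163 TPM, Lgals3, which encodes galectin-3, 5.76-fold and the glycoprotein Gpnmb 3.79-fold. The pair that rose, chosen after their values were seen, was Fabp5 (812 to 1587 TPM) and Ctsl (892 to 1017 TPM). All 24 cell cycle genes fell, also adjusted over the list alone, by a median log2 fold change of -2.77 (camera adjusted p = 5.6e-12; adjusted p = 0.082 with an estimated correlation). Cyclin B2 (Ccnb2) went from 39.7 to 1.97 TPM, cyclin A2 (Ccna2) from 21.6 to 0.833 TPM and Cdk1, the kinase of mitotic entry, from 35.7 ± 0.810 to 4.24 ± 0.193 TPM.

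Endoplasmic reticulum stress and amino acid response genes rose in 17 of 20 cases and fell in 2, with the same counts adjusted over the list alone (camera adjusted p = 5.2e-11; 0.017 with an estimated correlation). The glutathione-degrading Chac1 rose 5.11-fold, Trib3 3.88-fold and the stress transcription factor Ddit3 2.96-fold. Extracellular matrix genes rose in 9 and fell in 6 of 16 cases, also adjusted over the list alone (camera adjusted p = 0.012; adjusted p = 0.31 with an estimated correlation). The matrix proteases Mmp9 (15.7 to 1041 TPM) and Mmp14 (6.87 to 94.7 TPM) rose, and the protease inhibitor Timp2 fell from 399 to 85.1 TPM. Microglial genes of pain signalling went both ways, 9 higher and 8 lower of 18, also adjusted over the list alone (camera adjusted p = 0.044; adjusted p = 0.45 with an estimated correlation), with the adenosine receptor Adora2a rising from 0.0636 to 22.7 TPM and the cyclooxygenase Ptgs1 falling from 10.8 to 2.20 TPM. Ribosomal protein genes fell in 49 of 51 cases, also adjusted over the list alone (camera adjusted p = 9.5e-05; adjusted p = 0.57 with an estimated correlation), but only 18 fell under median-of-ratios scaling and 46 under quantile normalization. Rpl10a fell 1.58-fold.

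Markers of astrocytes and of the oligodendrocyte lineage fell in most cases, while of 8 neuron markers 1 rose and 2 fell. Astrocyte markers fell in 11 of 13 cases (9 under median-of-ratios scaling; 5 lower and 1 higher under quantile normalization), for example Gfap from 23.1 to 9.58 TPM and Aldoc from 16.4 to 6.10 TPM. Oligodendrocyte lineage markers fell in 12 of 14 cases (6 lower and 1 higher under median-of-ratios scaling, 8 and 1 under quantile normalization), for example Cspg4 from 24.2 to 3.89 TPM and Mbp from 187 to 121 TPM. Adjusted over the list alone, 11 and 12 fell, and neither list passed the camera test (adjusted p = 0.094 and 0.11).

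With limma, 2437 genes were higher and 7768 lower in sham sEV than in PBS at an adjusted p under 0.05, 68.9% of those tested, and 726 and 1475 of them differed at least 2-fold. The groups did not overlap for 9841 genes (66.5%), a part of which chance alone would give for 3 against 4 libraries. Of the 24 lists tested, 12 were called with camera's preset correlation and 3 with an estimated one. The excess of lower genes depended on scaling: the median log2 fold change of all genes was -0.25 on the deposited TPM and 0.00 under median-of-ratios scaling, which gave 4728 higher and 4579 lower genes, and quantile normalization gave 4307 and 4883. Median-of-ratios scaling was applied to the lists after seeing the data. The list calls of matrix and pain signalling genes ended under both scalings (camera adjusted p = 0.16 and 0.10 for matrix, 0.14 and 0.56 for pain signalling), and the second also without PBS replicates 2 and 3 (0.054 and 0.061).

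SNI sEVs against PBS asks the same of vesicles from animals with the nerve injury. Fewer genes were called than for sham sEVs, and all 32 interferon-stimulated genes were among those that rose, though the list lost its call with an estimated correlation (camera adjusted p = 0.070). Ccl5 rose to 501 ± 79.1 TPM (SD, n = 3) from 22.6 ± 6.73 TPM in PBS (SD, n = 4), Marco 8.18-fold to 135 ± 15.5 TPM, and the antiviral enzyme Oas3 to 31.0 ± 2.71 from 3.37 ± 1.75 TPM. Irf7, the transcription factor that amplifies interferon production, rose to 129 ± 16.1 from 24.3 ± 7.56 TPM (log2 fold change 2.40 ± 0.17 SE, limma adjusted p = 1.6e-05).

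The 10 largest rises were Ccl5, Slc13a3, Marco, Oas3, Fpr1, Irf7, Oas2, Zbp1, the non-classical class I gene H2-T24 and Ifit1, from 4.83-fold for Ifit1 to 21.9-fold for Ccl5. The largest falls were smaller. Lsp1 went from 73.4 ± 3.65 to 33.0 ± 4.80 TPM (2.20-fold), and the others were Ltc4s, the synthase of leukotriene C4, Ifi27, the thrombin receptor F2rl2, the organic anion transporter Slco2b1, Asb10, the hypoxia-induced Ankrd37, Dcstamp, which acts in the fusion of macrophages, the urokinase receptor Plaur (1.52-fold) and Mir1198, a microRNA entry for which no value is given. F2rl2 did not pass without SNI-sEV replicates 1 and 2 (limma adjusted p = 0.080 and 0.054) and Asb10 without SNI-sEV replicate 1 (0.064). Over all alternatives F2rl2 did not pass in 4 of 22, Asb10 in 2 of 23 and Ankrd37 in 2 of 23, with adjusted p up to 0.080, 0.097 and 0.055. On GRCm38, Irf7 lies at chromosome 7, 141262706 to 141266481, minus strand, Ifit1 at chromosome 19, 34640871 to 34650009, plus strand and Oas3 at chromosome 5, 120753098 to 120777661, minus strand.

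All 32 interferon-stimulated genes rose, also adjusted over the list alone, with a median log2 fold change of 1.47 (camera adjusted p = 1.4e-58; adjusted p = 0.070 with an estimated correlation). Ifi44 rose from 0.328 to 3.45 TPM and Zbp1 from 7.40 to 39.7 TPM. In antigen presentation 8 of 18 genes rose and 0 fell, or 11 and 3 adjusted over the list alone (camera adjusted p = 8.2e-07; adjusted p = 0.12 with an estimated correlation), with H2-K1 rising from 754 to 1309 TPM, the peptide transporter Tap1 1.68-fold and beta-2 microglobulin, B2m, 1.72-fold. Complement and phagocytic receptor genes rose in 8 of 18 cases and fell in 2, or 10 and 3 adjusted over the list alone (camera adjusted p = 8.2e-07; adjusted p = 0.055 with an estimated correlation). C3 rose from 114 to 419 TPM, Fcgr1 from 67.6 to 154 TPM and the complement gene C1qa 1.46-fold. Under median-of-ratios scaling 5 complement genes rose and 2 fell.

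Of 20 cytokines and chemokines, 5 rose and 0 fell, or 6 and 2 adjusted over the list alone (camera adjusted p = 0.0011; adjusted p = 0.20 with an estimated correlation). The 5 were Ccl5, Cxcl16 (1.35-fold), Cxcl9 (0.0779 to 0.521 TPM), Tnf (74.0 to 88.3 TPM) and Il1b (21.0 ± 5.04 to 45.1 ± 20.3 TPM). Cxcl9 thus averaged below 1 TPM in both groups and passed the filter only through sham sEV (6.80 TPM). The calls of Il1b, Tnf and Cxcl9 lay near the threshold. Without SNI-sEV replicate 1 their limma adjusted p were 0.085, 0.14 and 0.057, and Il1b also failed without PBS replicates 2 and 3 and each sham-sEV replicate (0.054 to 0.088), Tnf without PBS replicates 3 and 4, sham-sEV replicate 2 and SNI-sEV replicates 2 and 3 (0.052 to 0.090) and Cxcl9 without SNI-sEV replicate 2 (0.073). With the replicate block on the PBS and SNI-sEV libraries alone, an alternative chosen after seeing the data, Tnf had an adjusted p of 0.080. Scaling ended the call of Tnf under median-of-ratios scaling (0.076) and that of Cxcl9 under quantile normalization (0.20). Over all alternatives, Il1b did not pass in 10 of 23, Tnf in 10 of 23 and Cxcl9 in 3 of 22, with log2 fold changes of 0.68 to 1.19, 0.21 to 0.32 and 0.23 to 1.82 against 1.01, 0.25 and 0.50. Without a sham-sEV library these log2 fold changes stayed the same. Il6, Il1a and Nos2, chosen after their values were seen, did not pass the test, with means of 0.0682, 1.96 and 0.302 TPM against 0.0672, 1.88 and 0.152 TPM in PBS. In the NF-kappaB list 1 of 15 genes passed, Nfkbiz with 1.77-fold, or 2 adjusted over the list alone (camera adjusted p = 0.016; adjusted p = 0.55 with an estimated correlation). Border macrophage markers rose in 3 of 6 cases, also adjusted over the list alone, where 1 fell (camera adjusted p = 0.0013; adjusted p = 0.070 with an estimated correlation), among them Ms4a7 from 224 to 449.7 TPM and Cbr2 from 0.725 to 3.00 TPM. Extracellular matrix genes rose in 4 of 16 cases, or 5 adjusted over the list alone (camera adjusted p = 0.042; adjusted p = 0.55 with an estimated correlation), including Mmp9 (1.41-fold) and Mmp14 (1.43-fold), which did not pass without SNI-sEV replicate 1 (limma adjusted p = 0.052 and 0.089) or, for Mmp14, replicate 3 (0.062) and in 4 of 23 alternatives overall.

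Lists that fell did so by small amounts. Cell cycle genes fell in 8 of 24 cases, or 10 adjusted over the list alone (camera adjusted p = 2.5e-07; adjusted p = 0.20 with an estimated correlation), for example Ccnb2 from 39.7 to 26.8 TPM and Cdk1 from 35.7 ± 0.810 to 28.6 ± 0.588 TPM. Hypoxia and glycolysis genes fell in 8 of 21 cases, or 10 with 1 higher adjusted over the list alone (camera adjusted p = 5.0e-06; adjusted p = 0.22 with an estimated correlation), among them the glucose transporter Slc2a1 (1.23-fold) and enolase, Eno1 (1.25-fold), but only 5 fell under median-of-ratios scaling. Ribosomal protein genes fell in 3 of 51 cases, also adjusted over the list alone (camera adjusted p = 1.8e-05; adjusted p = 0.55 with an estimated correlation). Under median-of-ratios scaling limma called 0 of them, with 3 at an unadjusted p under 0.05, and under quantile normalization 2. Homeostatic genes (2 higher, 1 lower of 17) and disease-associated genes (2 and 2 of 20) had no list call. Of 13 astrocyte markers, also without a list call, 1 was higher. With the replicate block, camera also called disease-associated genes (adjusted p = 0.045), astrocyte markers (0.013), oligodendrocyte markers (0.011), neuron markers (0.032), pain signalling (0.016), cholesterol biosynthesis (0.016), respiratory chain (0.0098) and oxidative stress genes (0.032). Without the block these 8 lists had adjusted p of 0.45 to 0.56 with an estimated correlation, and fry called only oxidative stress genes (0.042, the others 0.20 to 0.52).

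With limma, 440 genes were higher and 350 lower in SNI sEV than in PBS, 5.34% of those tested, and 102 and 1 of these differed at least 2-fold. The groups did not overlap for 2568 genes (17.3%), a part of which chance alone would give for 3 against 4 libraries. Of the 24 lists, 10 were called with the preset correlation and 0 with an estimated one, where camera's unadjusted p was under 0.05 for 5 lists and fry called 8. With the replicate block, the preset correlation called 18. The count of lower genes rested on single libraries: it was 92, 119 and 158 without SNI-sEV replicates 1, 2 and 3, 653 and 151 without PBS replicates 1 and 3, 216 and 231 without sham-sEV replicates 2 and 3, and 127 with the replicate block on the PBS and SNI-sEV libraries alone, while the count of higher genes was 278 without SNI-sEV replicate 1. That block on these libraries alone kept 98 of the 350 lower genes and 313 of the 440 higher genes. Camera list calls ended for NF-kappaB genes without PBS replicates 2 and 3 and SNI-sEV replicate 1 (adjusted p = 0.074, 0.11 and 0.20), for ribosomal protein genes without PBS replicate 1 (0.13), and for matrix genes without any of PBS replicates 1, 2 and 3 or SNI-sEV replicate 1 or under either scaling (0.053 to 0.10), and 17 lists were called without PBS replicate 4.

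SNI sEVs against sham sEVs asks whether nerve injury changes the effect of the vesicles. Inflammatory genes were lower, and proliferation genes and many genes of the microglial state higher, after SNI sEVs than after sham sEVs. Il6 averaged 0.0682 ± 0.0262 TPM after SNI sEVs and 115 ± 7.38 TPM after sham sEVs (SD, n = 3 each; log2 fold change -6.76 ± 0.08 SE, limma adjusted p = 2.1e-12). Plau averaged 1338 ± 229 TPM after SNI sEVs and 34.8 TPM after sham sEVs, and Trem2 1181 ± 21.0 and 65.9 ± 7.26 TPM.

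The 10 largest falls were Il6, Il1a, Lcn2, Ptges, the terminal synthase of prostaglandin E, Il1b, Traf1, the myeloid receptor Cd300e, the inducible nitric oxide synthase Nos2, Mmp9 and Ccl5, from 36.8-fold for Ccl5 to 109-fold for Il6. Nos2 averaged 0.302 against 61.4 TPM, Ptges 3.41 against 237 TPM and Cd300e 1.64 against 134 TPM. The 10 largest rises were Plau, Hpgd, Rgs2, Dkk2, Rasgrp3, Pcp4l1, the growth factor-binding protein Igfbp5, Trem2, Lsp1 and Crip1, from 15.3-fold for Crip1 to 37.0-fold for Plau. Spp1, chosen after its values were seen, averaged 35949.8 against 4201 TPM.

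All 20 cytokines and chemokines were lower after SNI sEVs (camera adjusted p = 4.0e-23; 0.0065 with an estimated correlation), as were all 15 NF-kappaB genes (camera adjusted p = 1.1e-16; adjusted p = 0.070 with an estimated correlation), with Tnf at 88.3 against 544 TPM and Sod2 11.9-fold lower. Interferon-stimulated genes were lower in 31 of 32 cases (camera adjusted p = 2.7e-20; adjusted p = 0.17 with an estimated correlation). Oasl1 was 19.1-fold lower and Gbp2 9.47-fold lower, and Ifitm3, chosen after its values were seen, did not pass with 1778 against 1863 TPM but was called lower under median-of-ratios scaling (limma adjusted p = 0.017). These 3 lists had the same counts adjusted over the list alone, 20, 15 and 31. Antigen presentation genes were lower in 12 and higher in 5 of 18 cases (camera adjusted p = 7.6e-06; adjusted p = 0.12 with an estimated correlation), and complement and phagocytic receptor genes lower in 8 and higher in 2 of 18 (camera adjusted p = 0.00051; adjusted p = 0.070 with an estimated correlation), each also adjusted over the list alone. Antigen presentation had 13 lower and 2 higher under median-of-ratios scaling and 12 and 1 under quantile normalization. Complement had 15 lower and 2 higher under the first and 7 and 2 under the second. H2-K1 was 2.22-fold lower, Marco 36.2-fold lower and Cd68 2.61-fold higher. Endoplasmic reticulum stress genes were lower in 17 and higher in 2 of 20 cases, also adjusted over the list alone (camera adjusted p = 1.2e-12; 0.011 with an estimated correlation), with Chac1 5.46-fold lower.

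All 24 cell cycle genes were higher after SNI sEVs, also adjusted over the list alone (camera adjusted p = 4.9e-13; adjusted p = 0.070 with an estimated correlation), with Cdk1 at 28.6 ± 0.588 against 4.24 ± 0.193 TPM and Ccna2 10.8-fold higher. Homeostatic genes were higher in 14 and lower in 1 of 17 cases, or 15 and 1 adjusted over the list alone (camera adjusted p = 0.0069; adjusted p = 0.18 with an estimated correlation), Cx3cr1 7.45-fold. Disease-associated genes were higher in 16 and lower in 1 of 20 cases, also adjusted over the list alone (camera adjusted p = 0.00014; adjusted p = 0.17 with an estimated correlation), Lgals3 5.22-fold and Cd9 4.46-fold. Ribosomal protein genes were higher in 42 of 51 cases, or 44 adjusted over the list alone (camera adjusted p = 0.0022; adjusted p = 0.60 with an estimated correlation), but in 8 with 1 lower under median-of-ratios scaling. Quantile normalization kept 42 higher and 0 lower. Astrocyte markers were higher in 11 of 13 cases (10 under median-of-ratios scaling) and oligodendrocyte markers in 13 of 14 (7 with 1 lower), also adjusted over the list alone (camera adjusted p = 0.038 and 0.041; adjusted p = 0.49 and 0.49 with an estimated correlation). Gfap was 2.41-fold and Cspg4 5.13-fold higher.

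A further 4 lists with mixed members were called as lower by camera. Camera compares a list with all other genes, and the median log2 fold change of all genes here was 0.24. A list can thus be called lower without falling, and the median of the respiratory chain genes was -0.00947. Hypoxia and glycolysis genes were lower in 12 and higher in 6 of 21 cases, or 13 and 6 adjusted over the list alone (camera adjusted p = 0.00057; adjusted p = 0.30 with an estimated correlation), with hexokinase, Hk2, 3.99-fold lower. Oxidative stress genes were lower in 6 and higher in 5 of 18 cases, also adjusted over the list alone (camera adjusted p = 0.015; adjusted p = 0.17 with an estimated correlation), with glutathione reductase, Gsr, 3.22-fold lower. This balance depended on the scaling, with 11 lower and 3 higher under median-of-ratios scaling and 8 and 3 under quantile normalization. Extracellular matrix genes were lower in 7 and higher in 6 of 16 cases, also adjusted over the list alone (camera adjusted p = 0.041; adjusted p = 0.45 with an estimated correlation), with a median of 0.09 and a mean of -0.48 on the log2 scale, Mmp14 8.59-fold lower and Timp2 4.46-fold higher. Respiratory chain genes were lower in 4 and higher in 4 of 22 cases, or 3 and 4 adjusted over the list alone (camera adjusted p = 0.038; adjusted p = 0.49 with an estimated correlation). Under median-of-ratios scaling 15 were lower and 0 higher, and under quantile normalization 4 and 4.

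**Figure D2:**
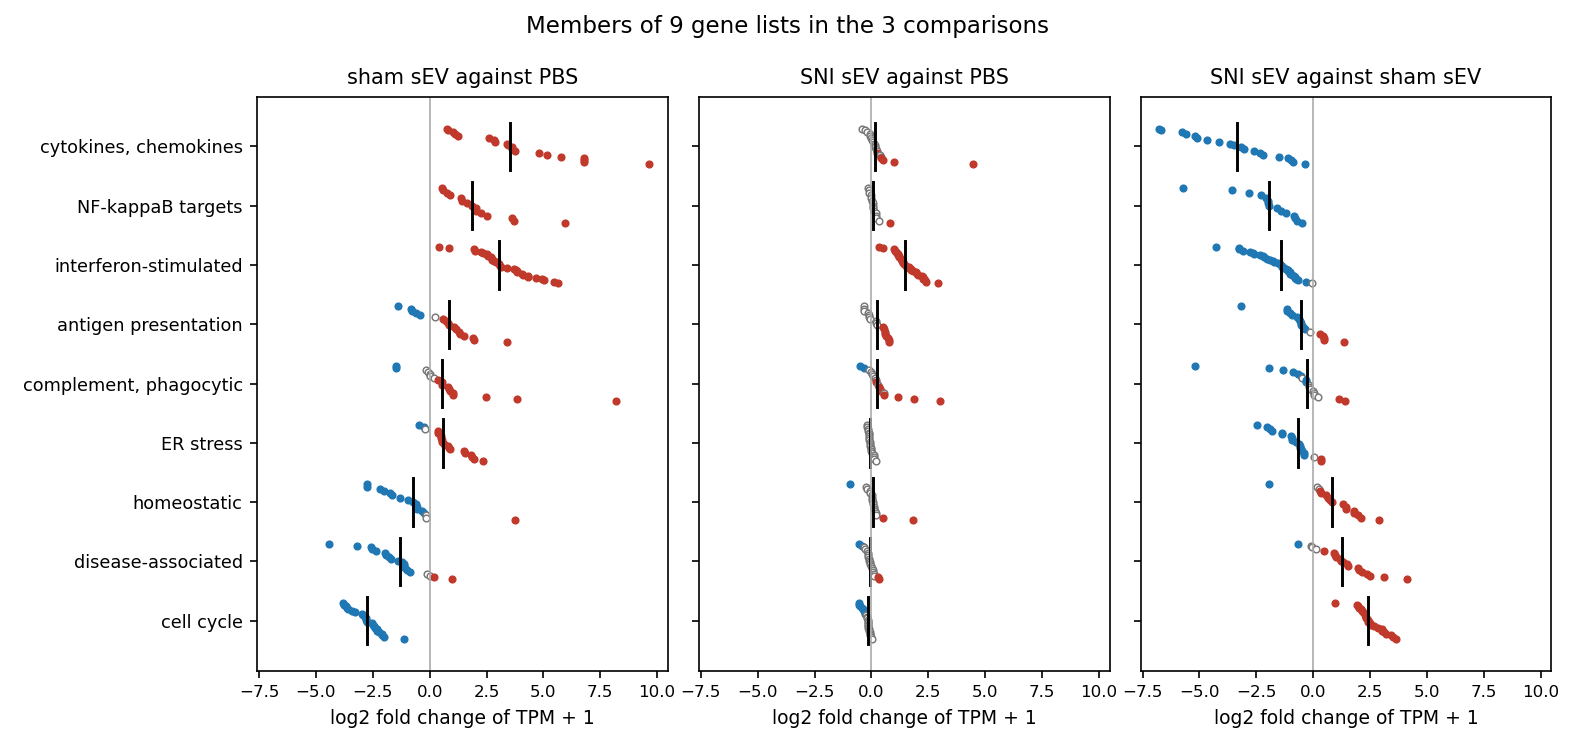
Log2 fold change of TPM + 1 for each tested member (point) of 9 gene lists in the 3 comparisons, on 1 horizontal range. Red points passed the test as higher, blue as lower, open points did not pass, and black bars are list medians. The median of the interferon-stimulated genes was 3.06 for sham sEV against PBS and 1.47 for SNI sEV against PBS, and that of the cytokines and chemokines 3.52 and 0.15.

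With limma, 7388 genes were higher and 2319 lower in SNI sEV than in sham sEV, 65.6% of those tested, and 1314 and 576 differed at least 2-fold. The groups did not overlap for 11568 genes (78.1%; chance alone gives 10% for 3 against 3). Of the 24 lists, 16 were called with the preset correlation and 2 with an estimated one. The balance again depended on scaling: the median log2 fold change of all genes was 0.24 on the deposited TPM, and median-of-ratios scaling gave 4250 higher and 4466 lower genes, quantile normalization 4373 and 4130. Camera list calls ended under median-of-ratios scaling for ribosomal protein and matrix genes (adjusted p = 0.33 and 0.34), under quantile normalization for matrix, complement, oxidative stress and respiratory chain genes (0.18, 0.084, 0.10 and 0.61), without PBS replicate 1 for astrocyte, oligodendrocyte and matrix genes (0.067, 0.057 and 0.056), without SNI-sEV replicate 2 for oligodendrocyte, matrix and respiratory chain genes (0.053 each), without sham-sEV replicate 1 for oligodendrocyte and matrix genes (0.054 each) and without sham-sEV replicate 3 for oligodendrocyte genes (0.052).

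Both vesicle groups can be set side by side through their shared PBS libraries. Of the 440 genes higher after SNI sEVs than in PBS, 402 (91.4%) were also higher after sham sEVs, and of the 350 lower genes 277 (79.1%) were also lower. 31 genes were called in opposite directions. Independent lists of the same sizes would share 72.4 and 184 genes. With the PBS libraries split 2 and 2 between the comparisons, the 6 splits shared 252 to 455 higher genes and 79 to 530 lower genes. Independent lists of the sizes in these splits would share 44.4 to 103 higher and 43.0 to 366 lower genes. The overlap was not computed under median-of-ratios scaling or quantile normalization. The log2 fold changes correlated across genes at 0.57, against 0.43 for 100 simulated pairs of unchanged groups against the same PBS libraries, and their covariance was 0.109 against 0.00514, a difference of 0.104. The simulated libraries were drawn independently, so the pairing of PBS and SNI-sEV libraries was not kept in them. Ccl5 and Marco rose in both, 806-fold and 296-fold after sham sEVs and 21.9-fold and 8.18-fold after SNI sEVs. Without SNI-sEV replicates 1, 2 and 3 the shared genes of both directions were 338, 404 and 445, against 679 with all libraries.

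The deposited table of differential genes lists 2375 genes with the authors' fold changes and false discovery rates for the same 3 comparisons. At a false discovery rate under 0.05 and at least 2-fold it holds 1307 higher and 623 lower genes for SNI sEV against sham sEV, 54 and 1 for SNI sEV against PBS, and 787 and 1487 for sham sEV against PBS. Of its genes under 0.05 that were tested here, limma called 2256 of 2259, 145 of 148 and 2273 of 2273. All 2375 genes in the table pass both limits in at least 1 comparison, so it is a selected list. It also rests on the same TPM values, so these high shares are no independent support. The table's fold changes equal the ratios of geometric means of TPM + 1 to within 3.7e-15 on the log2 scale, so the same sign in both is fixed by construction. The largest entries of the table are among those named above, such as Ccl5, Marco and Slc13a3 against PBS and Il6, Il1a and Plau between the vesicle groups. Of its 5 largest falls of SNI sEV against PBS with a false discovery rate under 0.05, Ccnb2, the mitotic genes Psrc1 (1.49-fold) and Cenpa (1.47-fold) and the epoxide hydrolase Ephx1 (1.45-fold) follow Lsp1. In the other direction, limma called 103 genes at least 2-fold for SNI sEV against PBS, 101 of them in the table, where 55 pass. Several genes named above for this comparison did not pass there. The authors' false discovery rates were 0.058 for Ifit1, 0.055 for Oas2 and 0.30 for Il1b. For Ltc4s, Ifi27, F2rl2, Slco2b1, Asb10, Ankrd37, Dcstamp and Plaur they were 0.069 to 0.20. Lsp1 and the other largest rises were under 0.05.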

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

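The tests below of blood cells, single mislabelled libraries, a shared batch and mixed RNA were chosen after the result they concern was seen.

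Within the PBS group, 73 items were checked for a library whose gap to the nearest other exceeds what 4 values normally show, which chance alone would find in 3.65 items. 11 were found, 6 of them in PBS replicate 1 and the rest in PBS replicate 2. PBS replicate 2 had the highest interferon-stimulated genes, with a list mean of 4.32 on the log2 scale against 3.62 to 3.70 in the other PBS libraries, Ifit1 at 12.2 TPM (5.15 to 5.31), Irf7 at 35.4 TPM (19.6 to 22.2), Oas3 at 5.98 TPM (2.23 to 2.67) and Zbp1 at 10.1 TPM (6.37 to 6.70). PBS replicate 1 had list means on the log2 scale of 4.94 for cell cycle genes (5.10 to 5.12 in the others), 7.67 for the respiratory chain (7.51 to 7.53), 8.17 for ribosomal protein genes (7.92 to 7.94) and 5.39 for endoplasmic reticulum stress genes (5.46 to 5.47), with Rasgrp3 at 157 TPM (210.0 to 216) and 18.6% of its TPM in pseudogenes (16.9 to 17.0%). With both libraries left out, an alternative chosen after seeing the data, SNI sEV against PBS gave 512 higher and 798 lower genes, and sham sEV against PBS 2471 and 8511.

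The sham-sEV cultures stood far from PBS in inflammatory, cell cycle and microglial state genes, and library measures moved with them: mitochondrial ribosomal RNA (997 ± 118 against 497 ± 92.4 TPM), the share of the 10 most abundant genes (20.5% against 17.2%) and that of pseudogenes (14.3% against 17.4%). A few abundant genes taking a share of the TPM total did not account for the change, since 1993 genes still differed at least 2-fold under median-of-ratios scaling against 2201 before. Blood cells mixed into the cultures stay open, as 6 of the 9 lymphocyte and neutrophil markers used had a sham-sEV mean below 1 TPM, while Lcn2 (1860.0 TPM), Camp (6.13 TPM) and S100a8 (32.1 TPM), which activated microglia may also express, rose, and monocytes were not tested. Single mislabelled libraries are argued against by all 10 libraries correlating best with their own group. The vesicles' origin in sham or SNI mice cannot be told apart from a batch, culture or vesicle preparation shared by the whole group, or from groups exchanged as a whole, because 0 label fields give one. The sham-sEV libraries could have been made apart, since same-numbered PBS and SNI-sEV libraries deviated together (0.154 to 0.363) and same-numbered PBS and sham-sEV libraries did not (-0.0176 to 0.0512). These correlations cannot decide it, as different-numbered pairs reached 0.220 for PBS and SNI sEV and 0.161 for PBS and sham sEV.

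Interferon-stimulated genes rose after SNI sEVs while most cytokines did not pass the test. As a list the cytokines and chemokines were also called higher (camera adjusted p = 0.0011). With an estimated correlation neither list passed (camera adjusted p = 0.070 for interferon-stimulated genes and 0.20 for cytokines). Sham-sEV RNA mixed into the SNI-sEV libraries would give every gene the same share of its sham-sEV rise, whereas the median share was 27.4% for the 32 interferon-stimulated genes (quartiles 14.5 to 41.7%) and 0.582% for the 20 cytokines and chemokines (-0.0675 to 3.10%), a ratio of 47.1, which excludes mixing as the whole cause. A single PBS library is excluded too, as at least 31 of the 32 genes were called with any 1 PBS library left out. A batch shared by the SNI-sEV libraries was not tested, for the reason given above. A response to the SNI vesicles may account for the pattern, as a hypothesis that came from these data and was not tested.

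More genes were lower than higher after sham sEVs, 76.1% of the calls. Without pseudogenes 79.0% were lower, with the remaining values rescaled to the same total. This cannot decide whether reads shared with pseudogenes play a part, because it returns no reads to the genes they resemble. The pseudogene share was 14.3% in sham sEV and 17.4% in PBS, so the rescaling by itself lowers sham-sEV values relative to PBS. Scaling of TPM to a fixed total cannot be told apart from a true general decrease: 49.2% of the calls were lower under median-of-ratios scaling, but that scaling centres the genes, which fixes the balance.

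Other splits of the same libraries into groups of the same sizes were counted. For SNI sEV against PBS, 440 higher and 350 lower genes were each reached by 1 of the 35 splits, the real one. The highest others gave 132 and 190. This is the fewest possible, and it treats the libraries as unpaired. Chance is thus made less likely for both counts but is not excluded, and within the pairs the splits are too few. The 10 list calls of SNI sEV against PBS were reached by 9 splits, the highest other giving 17, so chance is not excluded for them either. Among the 8 splits that part all 3 pairs of PBS and SNI-sEV libraries, the highest other gave 0 higher and 0 lower genes by limma and 16 lists, and the splits that part fewer pairs gave at most 132, 190 and 17. For sham sEV against PBS, 7768 lower genes were reached by 1 of 35 splits (highest other 1491), again the fewest possible. 2437 higher genes were reached by 3, the highest other giving 5793, and these others set 3 PBS libraries against the remaining PBS library with the sham-sEV libraries, a structure that keeps most of the real contrast with its direction turned. Their higher genes thus match the real lower genes, so 5793 rather than 1491 is the value to set beside 7768. Counted in both directions together, the real split called 10205 genes and the highest other 6787. The 12 list calls were reached by 15 splits (highest other 14), so chance is not excluded for them. For SNI sEV against sham sEV the 10 splits are too few: the real values were 7388, 2319 and 16 lists, reached by 1, 1 and 2 splits, and the highest others 0, 0 and 16.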

How the results depend on the processing

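The alternatives that left out pseudogenes or PBS libraries 1 and 2, fitted the replicate block to the PBS and SNI-sEV libraries alone, or applied median-of-ratios scaling to the gene lists were chosen after seeing the data. Of 3794 values for 173 named gene results, 3710 kept their direction and side of the threshold, 72 no longer passed, 1 newly passed (Ifitm3 in SNI sEV against sham sEV under median-of-ratios scaling) and 11 changed sign. Apart from 2 of Cd86 in sham sEV against PBS, all values that no longer passed were of SNI sEV against PBS, with 43 of the results. Most genes were named for large changes or small p in these same data, which favours kept calls. Of 607 values for 38 called lists, 533 were kept and 74 no longer passed. Median-of-ratios scaling and quantile normalization moved the counts of higher and lower genes to 4250 and 4466, and 4373 and 4130, for SNI sEV against sham sEV, and to 4728 and 4579, and 4307 and 4883, for sham sEV against PBS. Both scalings bring the genes of all libraries to a common centre, so the more even balance follows from their construction. For SNI sEV against PBS, sample weights gave 1274 higher and 2728 lower genes, only the 2 groups compared 155 lower, PBS libraries 1 and 2 left out 798 lower and the replicate block on these groups alone 127 lower (335 higher). What moved these counts was not tested. Camera with an estimated correlation called 2 lists for SNI sEV against sham sEV, 0 for SNI sEV against PBS (5 at an unadjusted p under 0.05) and 3 for sham sEV against PBS. The replicate block raised the lists of SNI sEV against PBS from 10 to 18. PBS and sham-sEV, and sham-sEV and SNI-sEV, libraries share only a number, and there the block gave 2503 higher and 7528 lower genes against PBS and 7663 and 2427 between vesicles. The block ended no list call. Among named genes it ended that of Mt1 in SNI sEV against PBS, and on those groups alone also those of Hmox1, Nfe2l2 and Tnf. With each library left out in turn, genes higher and lower ranged over 6610 to 8267 and 1999 to 2642 for SNI sEV against sham sEV, 278 to 502 and 92 to 653 for SNI sEV against PBS, and 2151 to 2508 and 7144 to 8668 for sham sEV against PBS. Lists ranged over 13 to 17, 8 to 17 and 11 to 14, genes shared by both vesicle effects over 338 to 998, and deposited calls also called here over 4652 to 4697 (4674 with all libraries). A mean of at least 5 TPM ended the matrix list in all 3 comparisons, pain signalling in sham sEV against PBS (0.061) and the respiratory chain and oligodendrocyte lists between vesicles (0.054 each), and fry the NF-kappaB, ribosomal and matrix lists of SNI sEV against PBS and the respiratory chain list between vesicles. Sign changes were of genes that did not pass in SNI sEV against PBS: Il6 was at -0.11 under quantile normalization, -0.0203 without PBS libraries 1 and 2 and -0.0267 to 0.0501 with single libraries left out, Nos2 at -0.0369 and -0.00491 to 0.283, and Il1a at -0.0247 with sample weights and -0.0651 to 0.161. The depth is unknown, so what it limits cannot be given.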

Other observations

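Anti-inflammatory and metabolic genes split in the sham-sEV cultures, in lists that camera did not call. Of 12 genes of alternative activation, 6 were higher and 5 lower than in PBS, also adjusted over the list alone (camera adjusted p = 0.068). The signalling inhibitor Socs3 rose from 3.61 to 160.3 TPM and the cytokine Il10 from 0.0992 to 13.8 TPM, while the mannose receptor Mrc1 fell from 35.3 to 4.19 TPM. In lipid handling the lipid droplet protein Plin2 fell from 1024 ± 73.5 to 231 ± 8.99 TPM (SD, n = 4 and 3), the liver X receptor Nr1h3 rose 4.20-fold, and Dhcr7 of cholesterol synthesis fell 1.87-fold. Among glycolysis and hypoxia genes, hexokinase (Hk2) rose 4.57-fold and Adm 6.79-fold, and Ndrg1 fell 2.47-fold. The ferritin heavy chain Fth1 rose from 10459 to 28963 TPM, while the light chain Ftl1, chosen after its values were seen and with a near-identical copy in the annotation, fell from 10586 to 7086 TPM. The vesicle tetraspanins Cd9, Cd63 and Cd81 fell 5.92-fold, 2.12-fold and 1.48-fold, and the respiratory gene Cox5a rose 2.06-fold.

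As counts of higher and lower genes after sham sEVs against PBS, the other lists gave 3 and 4 of 12 for LXR and lipid efflux (2 and 4 adjusted over the list alone, 7 and 2 under median-of-ratios scaling), 5 and 5 of 19 for cholesterol biosynthesis (11 and 2), 5 and 6 of 21 for hypoxia and glycolysis (14 and 5), 5 and 6 of 18 for oxidative stress (11 and 4), 3 and 9 of 22 for the respiratory chain (11 and 0), 4 and 8 of 19 for vesicle biogenesis and uptake (10 and 6) and 6 and 6 of 13 for immediate early and heat shock genes (7 and 5). The counts of these last 6 were the same adjusted over the list alone. The balance of higher and lower genes in these lists thus depends on the scaling. After SNI sEVs at most 3 members of any of these lists other than hypoxia and glycolysis differed from PBS, the 3 being Nfe2l2, Hmox1 and Mt1 of the oxidative stress list, lower by 1.19, 1.20 and 1.38-fold. Without SNI-sEV replicate 1 their limma adjusted p were 0.085, 0.17 and 0.18, and without SNI-sEV replicate 2 0.093, 0.11 and 0.13, and with the replicate block on the PBS and SNI-sEV libraries alone 0.097, 0.090 and 0.13. Under median-of-ratios scaling and quantile normalization Hmox1 had 0.11 and 0.16 and Mt1 0.099 and 0.071. Nfe2l2 also failed without SNI-sEV replicate 3 (0.056), Hmox1 without PBS replicates 2 and 3 and each sham-sEV replicate (0.056 to 0.064), and Mt1 without PBS replicates 3 and 4, SNI-sEV replicate 3 and each sham-sEV replicate (0.069 to 0.14). Over all alternatives they did not pass in 5 of 23, 13 of 23 and 16 of 23, with log2 fold changes of -0.30 to -0.21, -0.31 to -0.17 and -0.57 to -0.35. Against sham sEVs, SNI sEVs gave 5 and 6 of 12 for alternative activation, 8 and 8 of 18 for pain signalling, 5 and 4 of 19 for cholesterol biosynthesis (2 and 10 under median-of-ratios scaling), 3 and 2 of 12 for LXR and lipid efflux (3 and 7), 8 and 4 of 19 for vesicle genes (6 and 9) and 6 and 7 of 13 for immediate early genes.

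Erythrocyte, platelet and albumin transcripts were low in every group, unlike 4 other liver transcripts. None of the 10 erythrocyte and platelet transcripts in the table reached a mean of 1 TPM, and Hba-a1 averaged 0.180 TPM in PBS, 0.0523 TPM in sham sEV and 0.0592 TPM in SNI sEV. Albumin (Alb) averaged at most 0.0293 TPM. Of the 4 liver transcripts above the filter, 1 rose and 3 fell in sham sEV against PBS, also adjusted over the list alone. Trf, which glia also express, fell from 651 to 149 TPM. All 3 tested fibroblast and mural markers (Postn 2.85-fold) and all 4 endothelial markers (Egfl7 2.52-fold) fell in sham sEV, of 8 neuron markers 1 rose and 2 fell (3 and 1 under median-of-ratios scaling), and of 6 border macrophage markers 3 rose and 2 fell, each also adjusted over the list alone. All 3 lymphocyte and neutrophil markers above the filter, Lcn2, Camp and S100a8, rose in sham sEV. Sex-linked transcripts gave 3 higher of 4 in SNI sEV against sham sEV on the deposited TPM, a direction that quantile normalization did not keep (1 lower). Of the genes encoded in the mitochondrial genome the table holds the ribosomal RNAs mt-Rnr1 and mt-Rnr2, which together averaged 497 ± 92.4 TPM in PBS, 997 ± 118 TPM in sham sEV and 582 ± 66.3 TPM in SNI sEV (SD). The others were not analysed here.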
